A study of Mus musculus with 74 samples.

How the data were processed

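RNA was measured by Smart-seq2 in 74 libraries of 1000 double-sorted cells each, from 5 immune cell types of tumor and spleen in C57BL/6J mice aged 3 or 12 months, 10 days after MC38 cells were placed under the skin. Per the labels, organs were harvested at a fixed morning hour into lysis buffer at one center, and sequencing followed the common pipeline of a mouse immunology consortium. The authors aligned reads to the mm10 build with STAR 2.5.3 and counted them per gene with featureCounts, and the deposited table holds raw counts for 49480 gene symbols, 1 column per library. The annotation release, the strand setting and the handling of multi-mapping reads are not given in the sources used here. Genes are therefore named by symbol alone, of which 46891 match a reference name table, and values of antisense transcripts, pseudogenes and close paralogs (the H2, Klrc, Gbp and Gzm families, for example) carry that uncertainty.

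Libraries were grouped by the sorted type, tissue and age in their titles into 20 groups. Titles give 3 months for 2 spleen dendritic cell libraries whose age tag gives 12 months, and the titles were followed. No label says that libraries with one replicate number share a mouse or a day, so the numbers were not used as pairs in the main tests, and nothing states that libraries of a group come from separate animals. P-values therefore measure only the spread between these libraries. A check of whether libraries with the same number resemble each other asked for a correlation of residuals over 0.1 in every one of at least 3 pairs. It was met in one comparison, tumor regulatory T cells across the ages, with correlations from 0.1029 to 0.3084, and a value with the replicate number as a block stands beside that result. The sex transcripts matched the labels in all libraries, and no pair of replicates held identical counts, with 103 pairs compared.

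For each cell type 4 comparisons were made, and these, the tests, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. Age effects were fitted within each tissue, and tumor against spleen (the mean over the ages) and the age by tissue interaction in a fit of the 4 groups of a type, with sex as a covariate in dendritic cells. Genes with too few counts were removed with the filterByExpr function, libraries were scaled by TMM, and edgeR 4.0.16 with limma 3.58.1 in R 4.3.3 fitted robust quasi-likelihood models, whose two-sided p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A gene is said to rise or fall only when past that threshold. Levels are counts scaled to the library total (CPM), as mean ± SD over libraries, and log2 fold changes come from the model. Where all libraries of a group had no count, the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts only levels are given. Intervals and such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

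Fixed lists of genes, 39 in all, of which 14 hold markers of other cells, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. For each list the members past the threshold over all genes are given beside those adjusted over the list alone. A single count for a list means that both were equal. Named genes follow a fixed rule. It takes the 5 highest and 5 lowest fold changes for tumor against spleen and for age in tumor, the 4 highest and 4 lowest for age in spleen, and the 3 smallest adjusted p-values per side for the interaction. These need libraries that do not overlap between the groups compared (within each age for the tissue comparison) and a mean of at least 10 CPM in the higher group, and they leave out predicted genes and antigen receptor segments. From each list that fits the type, the rule adds up to 4 members past the threshold by smallest adjusted p and up to 2 of the most abundant that were not. The text gives a selection of these genes. Foxp3, Ncr1 and other genes named for the sort or for the tests of cell admixture are outside that rule.

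Alternatives were DESeq2 size factors, no low-count filter, the Wald test of DESeq2 1.42.0, the replicate number as a block (replicate block), all 4 groups in one fit for the age effects, dendritic cells without the sex covariate, without the libraries of conflicting labels or with their age tags, and each library left out in turn. Where a fit leaves 1 library in a group, that library is assumed to vary like the other groups of the fit. After seeing the data, fits were added with the ribosomal share or the B cell marker level as a covariate, without ribosomal protein genes, and without libraries rich in ribosomal, macrophage or mitochondrial transcripts. Other splits of the samples into groups of the same sizes were counted, all of them for the age effects with at least 3 libraries per group, and 40 in all, drawn at random with the real one included, for the 4-group fits of each type. The 4-group fits of conventional CD4 T cells were included, although their tumor group at 3 months holds 2 libraries. Splits for age in tumor conventional CD4 T cells were not counted, as they are too few for a share under 0.05.

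The pipeline was tested on simulated data with the group sizes, levels and spread of each comparison. In these, 200 genes and a separate list of 20 were changed, and none of those called had the wrong sign. Recovery below refers to the 200. Between 0 and 19 unchanged genes were called per comparison, or 0% to 12.7% of the calls, a larger share than the threshold of 0.05 in 13 of 20 comparisons. For a log2 fold change of 1, spleen comparisons of age recovered between 32% (macrophages) and 60.8% (CD8 T cells) of the changed genes, and tumor comparisons between 13.8% (conventional CD4 T cells) and 49% (regulatory T cells). For a log2 fold change of 2 these were 77.9% to 92.6% and 70.8% to 89.2%. The interaction recovered 2.1% to 21.1% at 1 and 38.7% to 62.9% at 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.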

Results

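The series holds bulk RNA sequencing of immune cells sorted from the tumor and the spleen of young and aged C57BL/6J mice that carried subcutaneous MC38 tumors, a mouse colon carcinoma line, for 10 days. Libraries were made with Smart-seq2, a full-length cDNA protocol for small cell numbers, from 1000 double-sorted cells each. The 5 sorted types were macrophages (CD11b+ F4/80+), dendritic cells (CD11b+ CD11c+ MHC class II+), regulatory T cells (CD4+ CD25+), conventional CD4 T cells (CD4+ CD25-) and CD8 T cells. With 2 tissues and 2 ages, 3 and 12 months, these make 20 groups and 74 libraries. Groups hold 4 libraries each, except spleen dendritic cells at 12 and at 3 months, tumor dendritic cells at 12 months and spleen conventional CD4 T cells at 3 months with 3 each, and tumor conventional CD4 T cells at 3 months with 2. Replicate 1 of each of the 4 dendritic cell groups came from males, and the other 70 libraries came from females.

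Total counts per library ran from 1652812 to 9115858, with a median of 4679409.5. Macrophage libraries held 3291251 to 6661551 counts, dendritic cells 2924963 to 9115858, regulatory T cells 3271014 to 6680354, conventional CD4 T cells 1652812 to 5509923 and CD8 T cells 3047343 to 7348746. Between 16576 and 24475 genes had a count in each library. Most transcripts behind the sort gates were abundant where they belonged. Adgre1, which encodes F4/80, had a median of 556 CPM (counts scaled to the library total) in macrophages, and Itgax, which encodes CD11c, had 459 CPM in dendritic cells. Itgam, which encodes CD11b, had 741 CPM in macrophages but 135 CPM in dendritic cells, where single spleen libraries ran from 54.4 to 87 CPM. Foxp3, the defining transcription factor of regulatory T cells, had 1090 CPM in regulatory T cells and 79.8 CPM in conventional CD4 T cells, where single libraries ran from 21.2 to 354 CPM. Cd8a had 1130 CPM in CD8 T cells. Genes of the Y chromosome summed to between 324 and 568 CPM in the 4 male libraries and to at most 3.45 CPM in the females.

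Some libraries stood apart from the others of their group. In tumor dendritic cells, replicate 2 carried 23770 CPM of macrophage markers at 12 months and 21130 CPM at 3 months, against 4011 to 9316 CPM in the other libraries. In spleen dendritic cells, B cell markers summed to 3988 ± 789 CPM (SD, n = 3) at 12 months and to 1278 ± 914 CPM (SD, n = 3) at 3 months. Neutrophil markers in spleen macrophages ran from 11030 to 41290 CPM at 12 months and from 5572 to 15460 CPM at 3 months. In spleen conventional CD4 T cells at 3 months, ribosomal protein genes took 8.68% of the counts in replicate 1 and 11.8% in replicate 4, against 4.56% in replicate 3 and 3.84% to 4.41% at 12 months. The titles of 2 spleen dendritic cell libraries, replicates 3 and 4, give 3 months where their age tag gives 12 months, and they were grouped by title.

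**Figure D1:**
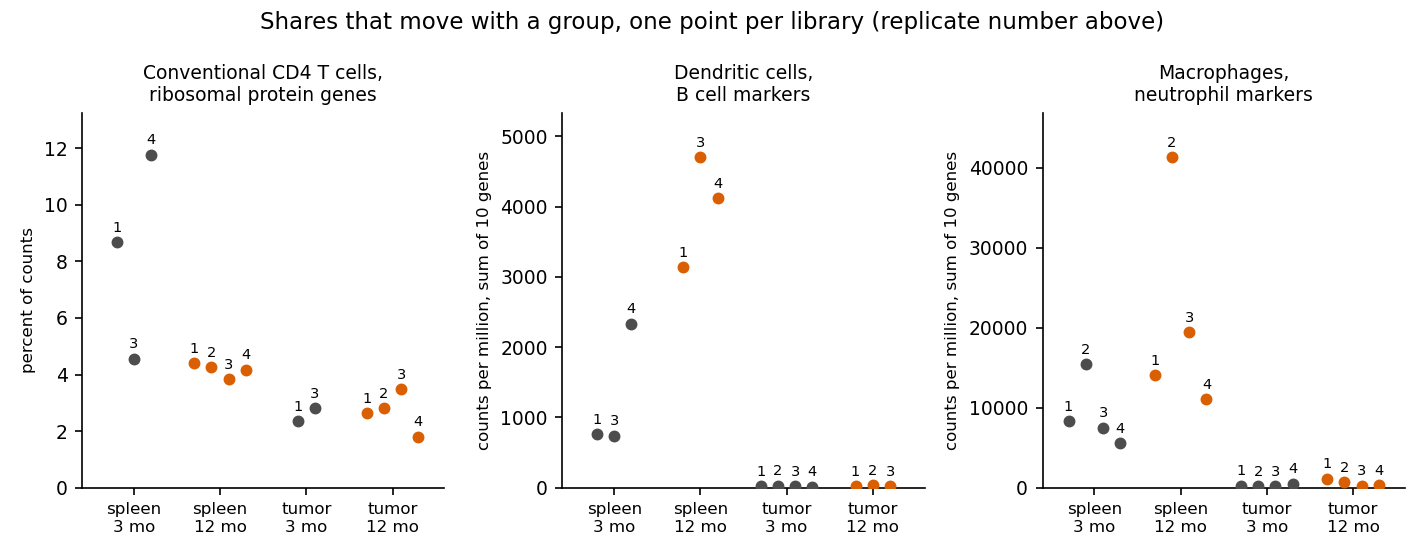
Ribosomal protein genes as a percent of counts in conventional CD4 T cells (left), the CPM sum of 10 B cell markers in dendritic cells (middle) and of 10 neutrophil markers in macrophages (right), with 1 point per library, gray at 3 months and orange at 12 months, and the replicate number above it. The shares of 8.68% and 11.8% in replicates 1 and 4 of spleen conventional CD4 T cells at 3 months lie above every other library in that panel.

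The series compares tumor-infiltrating and splenic immune cells between young and aged mice. Each cell type therefore has 4 comparisons here: tumor against spleen averaged over the ages, 12 against 3 months in spleen, 12 against 3 months in tumor, and the age by tissue interaction, which is the age effect in tumor minus the age effect in spleen. Log2 fold changes are tumor over spleen or 12 over 3 months, with their standard error (SE).

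**Figure D2:**
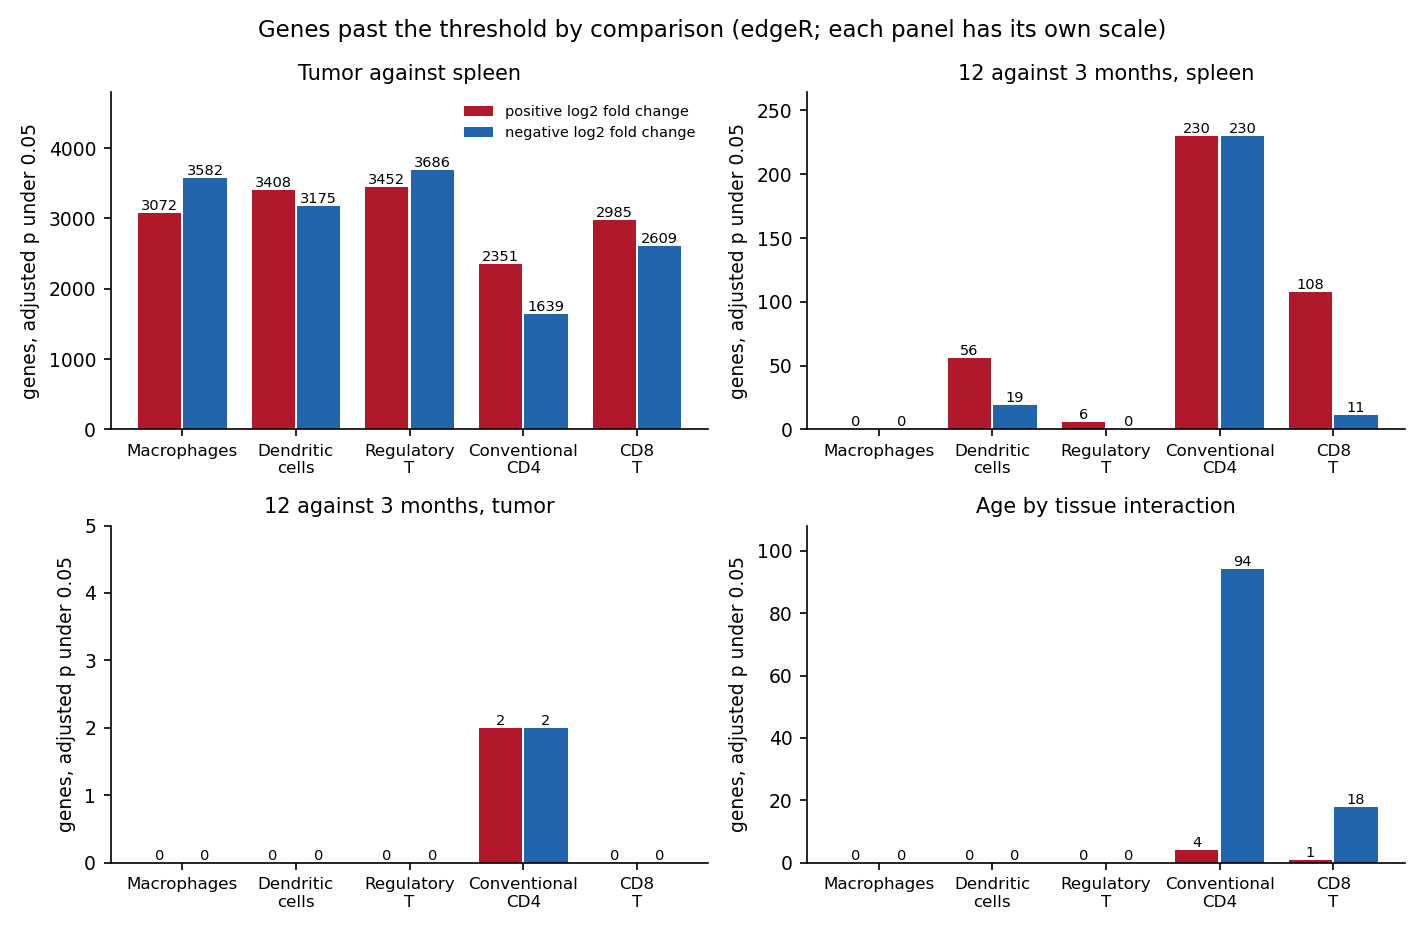
Number of genes with an adjusted p under 0.05 (edgeR) in each of the 4 comparisons for the 5 sorted cell types, as bars for positive and negative log2 fold changes, with each panel on its own scale. Counts run from 3990 to 7138 for tumor against spleen and from 0 to 4 for age in tumor, while age in spleen reached 460 in conventional CD4 T cells and 119 in CD8 T cells.

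Tumor CD8 T cells carried a strong activation and checkpoint program next to splenic CD8 T cells (n = 8 libraries each). Pdcd1, which encodes the inhibitory receptor PD-1, rose from 8.01 ± 3.88 to 493 ± 177 CPM (SD), a log2 fold change of 6.12 (SE 0.25), and Ifng, the interferon gamma gene, rose from 6.98 ± 4.79 to 453 ± 243 CPM. The costimulatory receptor gene Tnfrsf9 rose by 4.87 (SE 0.18), the regulator of G protein signaling Rgs16 by 7.83 (SE 0.49) and the death receptor ligand Fasl by 4.45 (SE 0.14). Lef1, a transcription factor of naive T cells, fell from 945 ± 116 to 149 ± 56.9 CPM. Gzmf and Siglecf had no count in any splenic library, so that their tumor levels of 88.2 ± 81.7 and 11.1 ± 11.5 CPM were at least 1230-fold and at least 154-fold higher. Siglecf is also an eosinophil marker, and the markers of eosinophils summed to 3.44 to 36.8 CPM in single tumor libraries and 0 to 4.42 CPM in splenic ones. Of 13285 genes tested, 2985 rose and 2609 fell.

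The gene groups moved broadly in these cells. In the checkpoint and exhaustion list 15 of 16 members rose, with a median of 4.59 (camera adjusted p = 5.21e-25), and in the cytotoxic effector list 20 of 21 rose and 1 fell, with a median of 3.59 (adjusted p = 6.02e-23). All 24 members of the type I interferon list rose, with a median of 2.35 (adjusted p = 2.12e-37), among them Isg15, up by 3.65 (SE 0.25), and the nucleic acid sensor Zbp1, up by 2.48 (SE 0.12). All 27 cell cycle genes rose, with a median of 2.26 (adjusted p = 3.05e-15), and the mitotic cyclin gene Ccnb1 rose by 2.63 (SE 0.30). All 14 naive and central memory genes fell, with a median of -1.85 (adjusted p = 2.68e-15), among them Id3, which fell by 2.45 (SE 0.16). Counts adjusted over the list alone were the same as those over all genes tested in these 5 lists, whose calls also held with an estimated correlation. The glycolytic enzyme gene Tpi1 rose from 36.5 ± 3.68 to 247 ± 60.3 CPM, while Eomes, a transcription factor of memory and exhausted cells, had a log2 fold change of -0.37 (SE 0.24, adjusted p = 0.229). All 8 B cell markers measured fell, with a median of -3.25 (adjusted p = 5.13e-05, and adjusted p = 0.0831 with an estimated correlation), their sum going from 78.4 to 163 CPM in single splenic libraries to 15.5 to 39 CPM in tumor.

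In the spleen, CD8 T cells from 12-month mice carried more transcripts of effector and memory genes than those from 3-month mice (n = 4 libraries each). Klrk1, which encodes the activating receptor NKG2D, rose from 58.9 ± 1.63 to 204 ± 28.8 CPM (SD), a log2 fold change of 1.80 (SE 0.13). The chemokine gene Ccl5 rose from 388 ± 135 to 1900 ± 449 CPM, Fasl from 7.16 ± 2.45 to 29 ± 3.51 CPM and Klrc1, an inhibitory NKG2 receptor gene, from 13.7 ± 3.74 to 60.1 ± 11 CPM. The protease inhibitor gene Serpina3g rose by 3.01 (SE 0.22) and the inflammatory caspase genes Casp1 and Casp4 by 2.83 (SE 0.27) and 2.58 (SE 0.30). The memory markers Cd44 and Il2rb rose by 0.82 (SE 0.12) and 0.66 (SE 0.12). Ccr9, a gut-homing chemokine receptor gene of naive CD8 T cells, fell from 315 ± 51.7 to 190 ± 25.8 CPM.

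By group, 9 of 17 cytotoxic effector genes rose in spleen CD8 T cells at 12 months, 14 when adjusted over the list alone, and all 17 had a positive fold change with a median of 1.43 (camera adjusted p = 2.83e-50, and adjusted p = 0.004 with an estimated correlation). In the memory and age-associated list 5 of 15 genes rose, 11 over the list alone, with a median of 0.82 (adjusted p = 6.66e-32). In the checkpoint list 4 of 14 rose, 6 over the list alone, with a median of 0.43 (adjusted p = 1.18e-09), among them Tigit, at 2.18 (SE 0.42), whose call was lost without replicate 1 at 12 months. The 3 NK cell markers measured, which CD8 effector cells also express, all rose, with a median of 1.71 (adjusted p = 1.98e-24), while Ncr1, an NK cell receptor gene, had no count at either age. None of 14 naive and central memory genes passed over all genes and 3 fell over the list alone, with a median of -0.17 (adjusted p = 0.000274). The memory, checkpoint, NK and naive lists held with an estimated correlation, at adjusted p = 0.00513, 0.0373, 0.00112 and 0.0373. Of 11677 genes tested, 108 rose and 11 fell at 12 months. The count of 119 dropped to 72 without replicate 1 at 12 months, to 73 without replicate 4 at 12 months and to 72 without replicate 3 at 3 months. It was 192 both without a low-count filter and with DESeq2, and 75 with all 4 groups in one fit.

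In the tumor, 0 of 11804 genes passed the threshold between CD8 T cells of 12 and 3 months with edgeR (n = 4 libraries each), 486 had an unadjusted p under 0.05, and DESeq2 called 12 and edgeR without a low-count filter 39. Ccl5 stood at 2290 ± 502 CPM at 12 months and 1560 ± 296 CPM at 3 months, a log2 fold change of 0.58 (SE 0.18, adjusted p = 1). Gzmb, a granule protease gene, stood at 2500 ± 333 and 2260 ± 369 CPM, and Pdcd1 at 440 ± 178 and 547 ± 185 CPM. The preset correlation put the glycolysis list at a median of 0.30 (adjusted p = 4.13e-06) and the tissue residence list at -0.30 (adjusted p = 9.96e-05), without a member past the threshold. Neither was kept, with adjusted p = 0.61 and adjusted p = 0.119 with an estimated correlation. The count was 2 without replicate 4 at 3 months and 4 without replicate 4 of both ages, whose mitochondrial shares of 8.34% and 9.26% lay above the 5.22% to 6.54% of the others, an alternative added after seeing the data.

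Several effector genes of CD8 T cells had a negative age by tissue interaction. For Klrk1 the interaction was -2.33 (SE 0.20, adjusted p = 4.7e-07), with 1000 ± 193 CPM at 3 months and 685 ± 120 CPM at 12 months in tumor. Klrc1 gave -2.67 (SE 0.34), its neighbor Klrc2 -2.97 (SE 0.30), Fasl -2.08 (SE 0.27) and Bhlhe40, a transcription factor of effector and resident T cells, -2.30 (SE 0.36). Cd44 gave -0.99 (SE 0.17). In the cytotoxic list 4 of 21 genes had a negative interaction past the threshold, 11 over the list alone, with a median of -1.72 (adjusted p = 4.1e-31). The memory list had 3 of 15, 7 over the list alone, with a median of -0.76 (adjusted p = 4.01e-19), and the tissue residence list 1 of 12, 6 over the list alone, with a median of -1.15 (adjusted p = 1.25e-11). All 3 lists held with an estimated correlation. Beside them, the 3 NK cell markers measured had 0 past the threshold, 2 negative over the list alone and a median of -1.73 (adjusted p = 0.000235, and adjusted p = 0.0157 with an estimated correlation), and tumor replicate 3 at 3 months held 304 CPM of these markers against 127 to 141 CPM in the others of its group. In total 1 gene had a positive and 18 had a negative interaction of 13285 tested. The count of 19 dropped to 12 without spleen replicate 2 or 3 at 3 months and rose to 29 without tumor replicate 4 at 3 months. It was 81 without a low-count filter and 48 with DESeq2, and 3 of 40 splits of the samples, the real one included, gave at least 19 genes, up to 36.

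**Figure D3:**
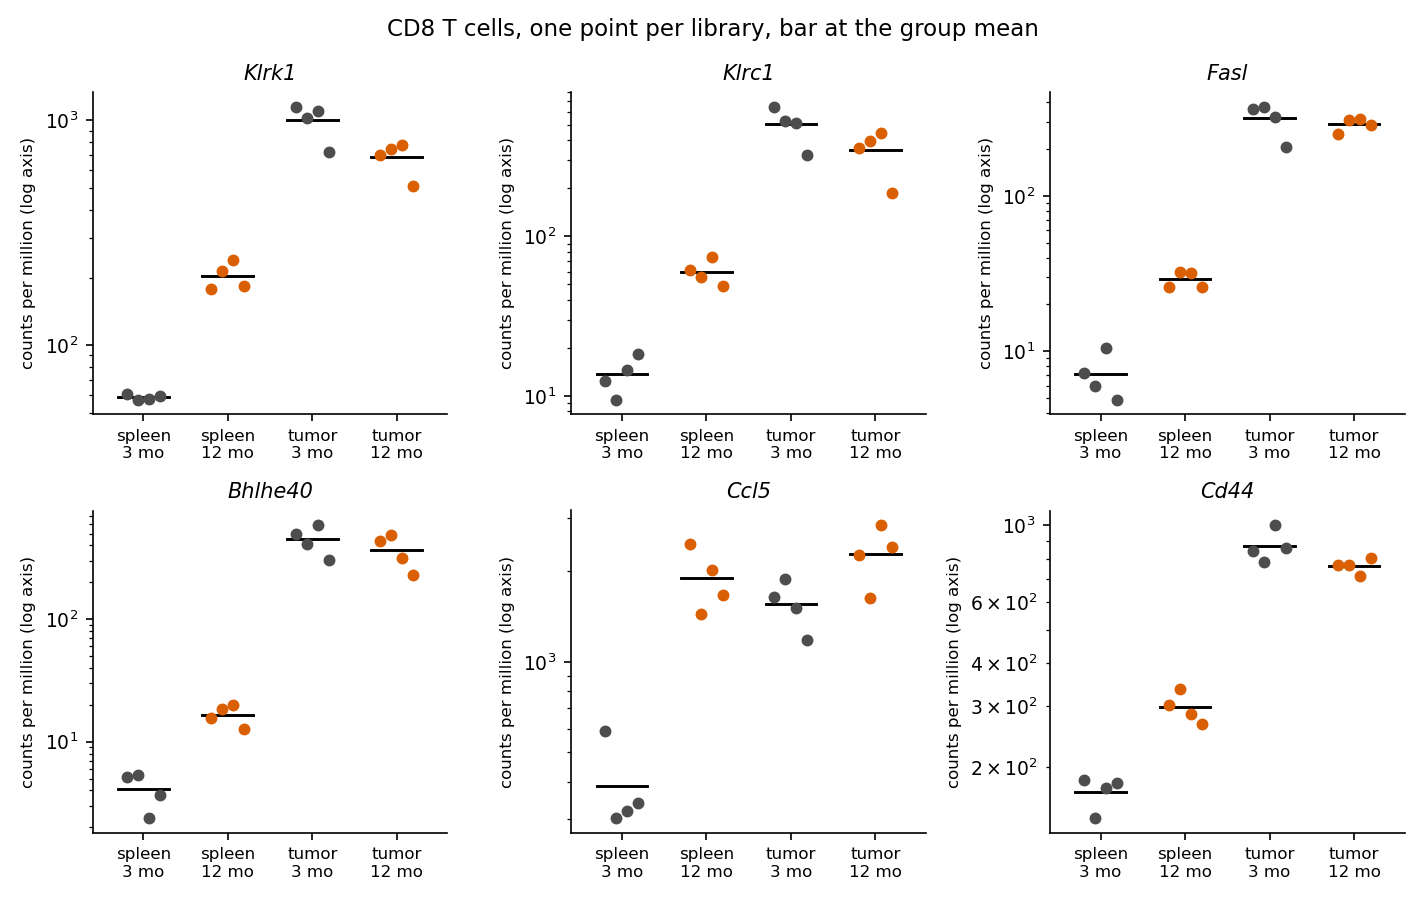
CPM on a log axis of 6 genes in CD8 T cells, by tissue and age, with 1 point per library, gray at 3 months and orange at 12 months, and a bar at the group mean. Klrk1 stands at means of 58.9 and 204 CPM in spleen at 3 and 12 months and at 1000 and 685 CPM in tumor.

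Conventional CD4 T cells of the tumor also differed widely from their splenic counterparts (n = 6 and 7 libraries). Gzmb rose from 4.5 ± 3.08 to 1530 ± 968 CPM (SD), a log2 fold change of 8.47 (SE 0.57), and Havcr2, which encodes the inhibitory receptor TIM-3, rose from 0.256 ± 0.329 to 61.3 ± 33.4 CPM. Tnfrsf9 rose by 4.21 (SE 0.21), Ifng by 3.54 (SE 0.32), the cytokine genes Csf2 and Il10 by 7.38 (SE 0.58) and 6.76 (SE 0.57), and the costimulatory receptor gene Icos by 3.26 (SE 0.17). Lef1 fell by 2.39 (SE 0.18). Il17a, at 9.5 ± 8.48 CPM in tumor and without a count in spleen, was at least 84.8-fold higher. Tumor regulatory T cells held Gzmb and Il10 at 7860 and 875 CPM and Foxp3 at 1132 ± 196 CPM at 12 months and 1153 ± 79.5 CPM at 3 months (n = 4 libraries each).

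Of the lists in tumor conventional CD4 T cells, all 24 type I interferon genes rose, with a median of 2.02 (camera adjusted p = 3.3e-41), and all 18 interferon gamma genes rose, with a median of 1.77. In the activated Treg list, which holds genes of activated regulatory cells, 18 of 20 rose and 2 fell, with a median of 2.42, and in the tissue residence list 10 of 12 rose, with a median of 2.77, such as Rgs1, which rose from 108 ± 37 to 1870 ± 183 CPM. Markers of regulatory T cells stood beside these genes, with Foxp3 at 76.1 to 354 CPM in single libraries of the tumor and 21.2 to 79.9 CPM in the spleen, and Il2ra, which encodes CD25, at 158 to 318 and 14 to 58.2 CPM. Both are members of the activated Treg list. Eosinophil markers summed to 23.6 to 87.3 CPM in tumor and 0 to 5.15 CPM in spleen. The naive list had 13 of 14 genes lower, with a median of -1.76. These lists held with an estimated correlation, at adjusted p = 0.00291, 0.00491, 6.09e-05, 0.000182 and 0.00158 in the order given, and their counts adjusted over the list alone were the same. Of 14661 genes tested, 2351 rose and 1639 fell, and fewer passed with the ribosomal share as a covariate, as given in the section on processing. The count of 3990 was 2465 without the 2 splenic libraries rich in ribosomal transcripts, 2238 of them shared with the full set.

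Conventional CD4 T cells of the spleen had 460 genes past the threshold between the ages (n = 4 libraries at 12 months and 3 at 3 months). Inhibitory receptor genes rose at 12 months, with Pdcd1 at 128 ± 24.1 against 30.2 ± 4.59 CPM (SD), Lag3 at 90.7 ± 23.2 against 8.47 ± 3.81 CPM and Tigit at 78 ± 2.7 against 13.1 ± 5.22 CPM. The cytokine gene Il21 rose by 4.37 (SE 0.54), Spp1, which encodes osteopontin, by 6.23 (SE 0.55), the granzyme gene Gzmk by 3.68 (SE 0.49) and Bhlhe40 by 3.13 (SE 0.30). Maf, a transcription factor that drives Il21 and Il10, rose from 108 ± 72.5 to 485 ± 67.3 CPM. Dapl1, a transcript of naive T cells, fell from 248 ± 115 to 47.6 ± 16.6 CPM.

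As groups, 6 of 15 checkpoint genes rose in these cells, 11 adjusted over the list alone, with a median of 1.24 (camera adjusted p = 1.04e-15), and 9 of 16 memory and age-associated genes rose, 12 over the list alone, with a median of 1.24 (adjusted p = 5.32e-17). The activated Treg list had 8 of 20 higher, 12 over the list alone, with a median of 0.68 (adjusted p = 6.18e-09), among them Nt5e, up by 1.77 (SE 0.22), and Nrp1, up by 2.20 (SE 0.30). The T helper list had 4 of 12 higher, 5 over the list alone, with a median of 0.81 (adjusted p = 1.71e-05). Foxp3 stood at 71.5 ± 13.4 against 32.5 ± 11.8 CPM. All 4 lists held with an estimated correlation, at adjusted p = 0.00798, 0.00821, 0.0233 and 0.0281.

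Oxidative phosphorylation genes moved the other way in spleen conventional CD4 T cells. There 5 of 19 fell at 12 months, 15 over the list alone, with a median of -0.63 (adjusted p = 6.25e-07, and adjusted p = 0.405 with an estimated correlation). They fell together with 67 of 84 ribosomal protein genes, such as Rpl38, at 47.2 ± 8.81 against 161 ± 113 CPM. The ribosomal share was 8.68% and 11.8% in replicates 1 and 4 at 3 months and 4.56% in replicate 3, and replicate 4 also held 7428 CPM of plasma cell markers, against 877 to 1088 CPM in the other splenic libraries of this type. Of 11726 genes tested, 230 rose and 230 fell. The count of 460 was 839 without a low-count filter and 881 with DESeq2. Single libraries moved it widely, to 88, 2400 and 137 without replicate 1, 3 or 4 at 3 months and to 165, 131, 123 and 128 without replicates 1 to 4 at 12 months. Without both ribosome-rich libraries, which leaves 1 library at 3 months that is assumed to vary like the 12-month group, 72 genes rose and 7 fell, of which 65 were shared with the 460.

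In tumor conventional CD4 T cells, 2 genes rose and 2 fell of 12882 tested between 12 months (n = 4 libraries) and 3 months (n = 2). Itgae, which encodes the epithelial adhesion integrin CD103, fell from 229 ± 59 to 79.6 ± 21.2 CPM (SD), by 1.54 (SE 0.24), and Itga4, an integrin gene of T cell homing, rose from 163 ± 17.1 to 431 ± 73.4 CPM, by 1.39 (SE 0.23). The inflammasome sensor gene Naip5 stood at 11.6 ± 2.18 against 0.0959 ± 0.136 CPM, and the fourth gene, C230085N15Rik, outside the naming rule and chosen after its values were seen, fell by 1.09 (SE 0.19). In the activated Treg list 1 of 20 fell, 8 fell and 1 rose over the list alone, with a median of -0.63 (adjusted p = 2.44e-11, and adjusted p = 0.0438 with an estimated correlation). The costimulatory gene Tnfrsf4 of that list stood at 1130 ± 175 against 1860 ± 64.6 CPM (adjusted p = 0.278). Foxp3 and Il2ra, also of that list, stood at 146 ± 59.4 against 290 ± 90.6 CPM and at 177 ± 13.7 against 303 ± 22 CPM. The 6 macrophage markers measured, none past the threshold, had a median of -1.56 beside them (adjusted p = 0.000115, and adjusted p = 0.523 with an estimated correlation). DESeq2 called 40 genes in this comparison, and edgeR without a low-count filter called 51. The count of 4 was 1 without replicate 1, 2 or 3 at 12 months, 11 without replicate 4 at 12 months or replicate 3 at 3 months and 0 without replicate 1 at 3 months. Leaving out either library at 3 months leaves 1, which is assumed to vary like the 12-month group. The calls of Itgae, Itga4 and Naip5 were each lost without replicate 2 at 12 months or replicate 1 at 3 months. Itga4 and Naip5 were also lost without replicate 1 at 12 months or replicate 3 at 3 months, and Itgae and Naip5 without replicate 3 at 12 months.

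The interaction was negative for 94 genes and positive for 4 of 14661 tested in conventional CD4 T cells. Bhlhe40 gave -3.66 (SE 0.35, adjusted p = 9.35e-07), with 118 ± 26.7 against 12.2 ± 5.86 CPM in spleen and 514 ± 80.5 against 720 ± 88.2 CPM in tumor at 12 and 3 months. Itgb8, an integrin that activates TGF-beta, gave -5.17 (SE 0.56), the activation marker Cd83 -3.79 (SE 0.49) and Itgae -3.19 (SE 0.46). Pdcd1, at 318 ± 48.8 against 282 ± 9.6 CPM in tumor, gave -1.79 (SE 0.28), and Tigit -2.78 (SE 0.43). In the activated Treg list 8 of 20 genes had a negative interaction, 13 over the list alone, with a median of -1.20 (adjusted p = 6.18e-21). Foxp3 of that list stood at 71.5 ± 13.4 against 32.5 ± 11.8 CPM in spleen and at 146 ± 59.4 against 290 ± 90.6 CPM in tumor, at 12 and 3 months. In the checkpoint list 5 of 16 genes had one, 10 over the list alone, with a median of -1.26 (adjusted p = 1.83e-14). The tissue residence list had 4 of 12 by both counts, with a median of -1.14, and the memory list 3 of 16, 8 over the list alone, with a median of -1.02. All 4 lists held with an estimated correlation, at adjusted p = 0.000208 for activated Treg and adjusted p = 0.00411 for the other lists. The count of 98 was 56 without spleen replicate 1 at 3 months, 640 without spleen replicate 3 at 3 months and 24 without tumor replicate 1 at 3 months, which leaves 1 library in that group. It was 261 without a low-count filter and 200 with DESeq2, and it was 43 without the 2 ribosome-rich libraries, 37 of them shared.

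**Figure D4:**
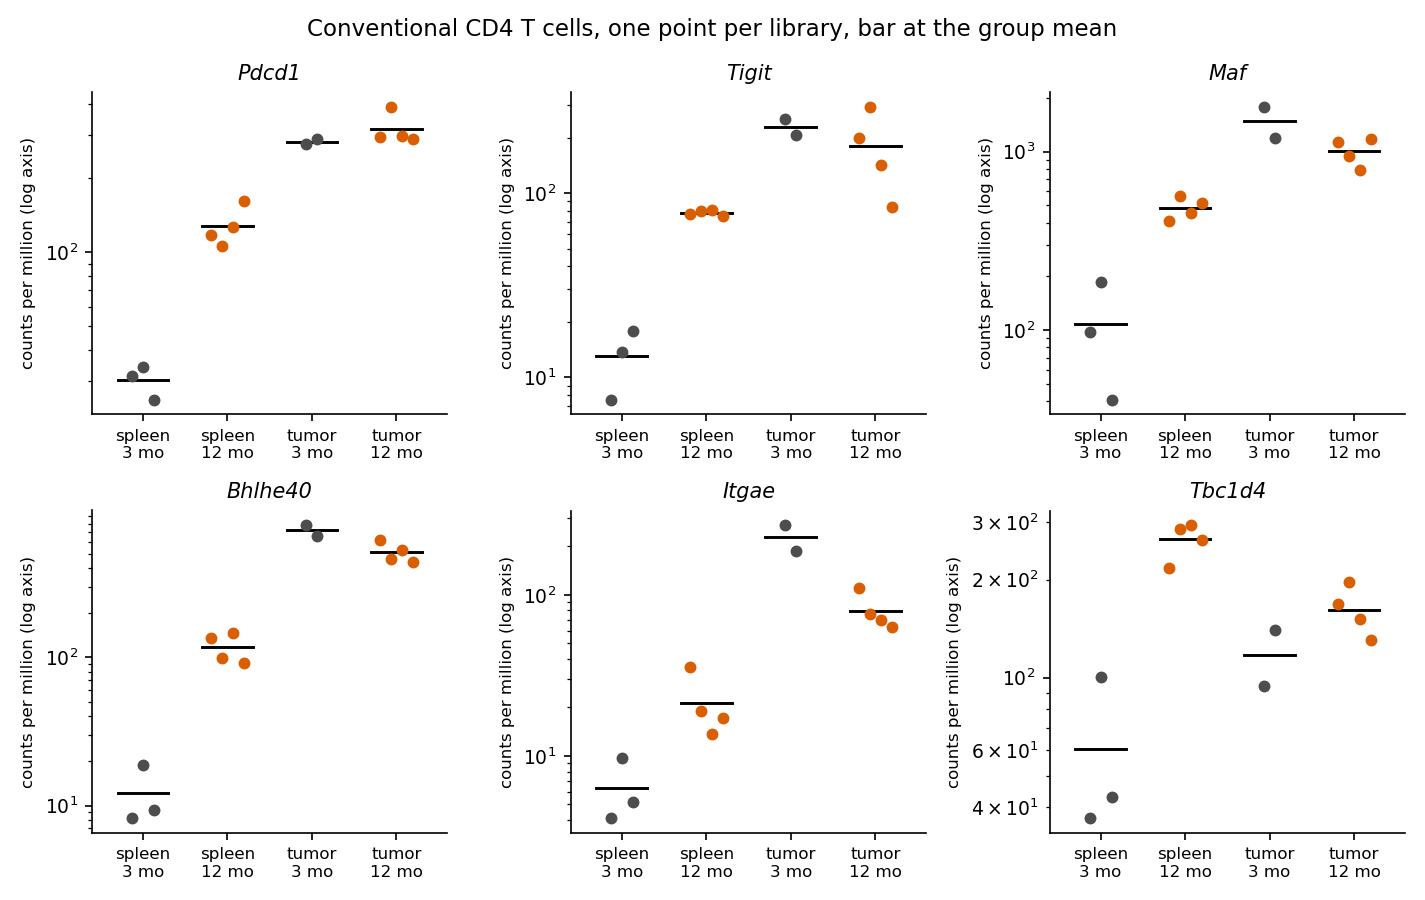
CPM on a log axis of 6 genes in conventional CD4 T cells, by tissue and age, with 1 point per library, gray at 3 months and orange at 12 months, and a bar at the group mean. Tigit stands at means of 13.1 and 78 CPM in spleen at 3 and 12 months and at 229 and 180 CPM in tumor.

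Regulatory T cells of the tumor expressed effector genes far above the level of splenic regulatory T cells (n = 8 libraries each). Gzmb rose from 51.4 ± 57.7 to 7860 ± 814 CPM (SD), a log2 fold change of 7.59 (SE 0.60), and the suppressive cytokine gene Il10 rose from 4.38 ± 2.38 to 875 ± 270 CPM. Tnfrsf9 rose by 3.72 (SE 0.09), the chemokine receptor gene Ccr8 by 3.30 (SE 0.13), Icos by 4.80 (SE 0.19) and Entpd1, which encodes the ectonucleotidase CD39, by 3.50 (SE 0.13). Tcf7, a transcription factor of naive and memory T cells, fell from 339 ± 39.1 to 0.579 ± 0.646 CPM, and Id3 fell by 6.44 (SE 0.29). Of 13345 genes tested, 3452 rose and 3686 fell.

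Among the lists, all 24 type I interferon genes rose in tumor regulatory T cells, with a median of 2.90 (camera adjusted p = 7.98e-36, and adjusted p = 0.0138 with an estimated correlation), and all 10 tissue residence genes rose, with a median of 2.76. In the activated Treg list 14 of 20 rose and 4 fell, with a median of 1.49, and 11 of 13 naive genes fell while 1 rose, with a median of -2.32 (adjusted p = 9.02e-19). The residence, activated Treg and naive lists held at adjusted p = 0.00294, 0.00428 and 0.000823 with an estimated correlation. The glycolysis list had 21 of 23 genes higher and 1 lower, with a median of 1.79 (adjusted p = 1.49e-18, and adjusted p = 0.0512 with an estimated correlation), among them the lactate exporter gene Slc16a3, up by 4.55 (SE 0.15). Counts adjusted over the list alone were the same in all 5 lists. Genes listed as markers of other cells differed as well. Of 10 neutrophil markers only 2 passed the low-count filter. Both rose, with a median of 7.95, or 7.03 with 1 member at its lower bound (adjusted p = 0.00257, and adjusted p = 0.0244 with an estimated correlation). Of these, Ltf rose from 0.634 ± 1.05 to 128 ± 50.8 CPM, while all 10 together summed to 69.7 to 237 CPM in single tumor libraries. In single libraries eosinophil markers summed to 34.9 to 113 CPM in tumor and 0 to 17.8 CPM in spleen, and dendritic cell markers to 35.1 to 138 and 659 to 871 CPM. Spleen conventional CD4 and CD8 T cells held these dendritic cell markers at similar levels, 685 to 1140 and 783 to 1185 CPM. Of 9 B cell markers 7 fell, 8 over the list alone, with a median of -1.69 (adjusted p = 0.00741, and adjusted p = 0.0884 with an estimated correlation).

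In the spleen, 6 genes of 12261 rose and 0 fell in regulatory T cells at 12 months (n = 4 libraries each). Il1r2, a decoy receptor gene for interleukin 1, rose from 27.7 ± 6.58 to 150 ± 40.3 CPM (SD), by 2.42 (SE 0.22). Ecel1 stood at 17.8 ± 5.42 CPM and had no count at 3 months, at least 98.3-fold higher. Lag3, an inhibitory receptor gene, stood at 107 ± 15.9 against 45 ± 12.7 CPM (adjusted p = 0.0274), and Apol10b, Ccdc80 and Sostdc1 had log2 fold changes of 3.51 (SE 0.48), 2.56 (SE 0.35) and 4.78 (SE 0.76). In the checkpoint list 1 of 16 rose, 5 over the list alone, with a median of 0.24 (adjusted p = 4.24e-06, and adjusted p = 0.312 with an estimated correlation). The count of 6 was 26 with DESeq2, 56 without a low-count filter and 3 with all 4 groups in one fit, and 2 of 35 splits of the samples, the real one included, gave at least 6 genes, up to 41. It was 2 without replicate 1 or replicate 2 at 12 months, which also ended the calls of Apol10b, Ccdc80, Lag3 and Sostdc1. Lag3 was further lost without replicate 4 at 12 months or replicates 1, 3 or 4 at 3 months, and Sostdc1 without replicates 3 or 4 at 12 months or replicates 1, 2 or 3 at 3 months.

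In tumor regulatory T cells 0 of 11698 genes passed between the ages with edgeR (n = 4 libraries each), 461 had an unadjusted p under 0.05, and DESeq2 called 7 and edgeR without a low-count filter 41. Gzmb stood at 8140 ± 708 CPM at 12 months and 7590 ± 921 CPM at 3 months, a log2 fold change of 0.09 (SE 0.14), and Il10 had 0.05 (SE 0.27). Replicates with the same number were alike across the ages in this group, and with the replicate number as a block 2 genes rose and 1 fell. Without replicate 4 of both ages, whose mitochondrial shares of 1.69% and 1.43% lay above the 0.865% to 1.07% of the others, the count was 1, an alternative added after seeing the data. For the interaction 0 of 13345 genes passed with edgeR, 521 had an unadjusted p under 0.05, and DESeq2 called 5 and edgeR without a low-count filter 13. The interferon gamma list had a median of -0.25 (adjusted p = 0.000381, and adjusted p = 0.51 with an estimated correlation). The interaction count was 1 without spleen replicate 3 at 12 months or tumor replicate 1 at 3 months, and 2 without spleen replicate 3 at 3 months or tumor replicate 4 at 3 months.

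Tumor macrophages expressed a phagocytic and interferon-responsive program that set them apart from splenic macrophages (n = 8 libraries each). Arg1, which encodes the arginine-degrading enzyme arginase 1, rose from 1.36 ± 1.47 to 4790 ± 2080 CPM (SD), a log2 fold change of 11.90 (SE 0.57), and the complement gene C1qb rose from 135 ± 49 to 4220 ± 1270 CPM. The lipid receptor gene Trem2 rose by 3.48 (SE 0.16), the lysosomal protease gene Lgmn by 4.09 (SE 0.14) and the T cell attracting chemokine gene Cxcl10 from 21 ± 8.1 to 641 ± 297 CPM. Of the genes of red pulp macrophages, which recycle iron in the spleen, the iron exporter gene Slc40a1 stood at 16.9 ± 15.8 against 625 ± 155 CPM and the scavenger receptor gene Cd5l fell by 6.27 (SE 0.49), while 3 other genes of the red pulp list rose. Il1b had a log2 fold change of -0.00 (SE 0.19, adjusted p = 0.989). Of 12876 genes tested, 3072 rose and 3582 fell.

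In the tumor-associated macrophage list 20 of 24 genes rose and 2 fell in tumor macrophages, 20 and 3 over the list alone, with a median of 3.39 (camera adjusted p = 6.46e-18, and adjusted p = 0.00205 with an estimated correlation). The lysosome and phagocytosis list had 14 of 16 higher, with a median of 1.55 (adjusted p = 1.72e-17), and the interferon gamma list all 20, with a median of 2.85 (adjusted p = 1.78e-19). All 24 glycolysis genes rose, with a median of 1.87 (adjusted p = 2.3e-24), such as Ldha, up by 2.21 (SE 0.12). These 3 lists held at adjusted p = 0.00205, 0.0463 and 0.0268 with an estimated correlation, whereas the type I interferon list, with all 24 genes higher and a median of 2.07 (adjusted p = 1.36e-18), did not, at adjusted p = 0.126 with an estimated correlation. In the red pulp list 3 of 10 rose and 6 fell, 4 and 6 over the list alone, with a median of -2.79 (adjusted p = 0.0418, and adjusted p = 0.349 with an estimated correlation). The splenic sort carried transcripts of other cells. All 10 B cell markers were lower in tumor, with a median of -8.32 (adjusted p = 1.7e-19), and all 10 neutrophil markers were lower, with a median of -5.83 (adjusted p = 3.98e-06, and adjusted p = 0.2 with an estimated correlation). Counts adjusted over the list alone were the same as over all genes, save where a second count is given.

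Between 12 and 3 months no macrophage gene passed the threshold with the low-count filter, and without it edgeR called 43 in tumor, 53 in spleen and 5 in the interaction. In tumor 0 of 11007 genes passed with edgeR (n = 4 libraries each), 663 had an unadjusted p under 0.05 and DESeq2 called 3. Arg1 stood at 6010 ± 1250 against 3570 ± 2130 CPM (log2 fold change 0.69, SE 0.37, adjusted p = 0.818). The interferon gamma list had a median of -0.39 (adjusted p = 3.9e-05, and adjusted p = 0.8 with an estimated correlation). In spleen 0 of 12131 genes passed, 736 had an unadjusted p under 0.05 and DESeq2 called 12. Il1b stood at 2330 ± 869 against 1460 ± 218 CPM (adjusted p = 0.736) and the cell cycle inhibitor gene Cdkn1a at 151 ± 37.9 against 248 ± 24.2 CPM (adjusted p = 0.698). The spleen list of neutrophil markers had a median of 1.11, 6 of 10 higher over the list alone (adjusted p = 1.11e-09, and adjusted p = 0.504 with an estimated correlation), beside the wide range of neutrophil transcripts in that sort. The interaction gave 0 of 12876 genes, 619 with an unadjusted p under 0.05 and 1 by DESeq2, and the red pulp list, with 0 of 10 past the threshold and 3 over the list alone, had a median of 0.83 (adjusted p = 3.73e-05, and adjusted p = 0.0605 with an estimated correlation). Without replicate 3 of the tumor at 12 months, 2 genes passed in tumor and 1 in the interaction.

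Tumor dendritic cells expressed inflammatory and immediate early genes at far higher levels than splenic dendritic cells (n = 7 and 6 libraries, with sex in the model). Cd14, a coreceptor for bacterial lipopolysaccharide, rose from 7.4 ± 4.86 to 1200 ± 360 CPM (SD), a log2 fold change of 7.76 (SE 0.33), and the cytokine gene Il1b rose from 134 ± 46.6 to 3750 ± 1100 CPM. The immediate early gene Fos rose from 99 ± 53.9 to 2430 ± 296 CPM, the chemokine receptor gene Ccr2 by 3.24 (SE 0.18) and Il12b, a subunit of interleukin 12, by 3.37 (SE 0.26). Clec4a4, a lectin receptor of splenic type 2 dendritic cells, fell from 143 ± 33.2 to 1.87 ± 1.37 CPM. Irf8, a transcription factor of type 1 dendritic cells, had a log2 fold change of 0.05 (SE 0.15, adjusted p = 0.831). Of 13981 genes tested, 3408 rose and 3175 fell.

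The inflammatory myeloid list had all 18 genes higher in tumor dendritic cells, with a median of 5.20 (camera adjusted p = 3.78e-22, and adjusted p = 0.00107 with an estimated correlation). The glycolysis list had 23 of 24 higher, with a median of 2.46 (adjusted p = 2.13e-45), such as the glucose transporter gene Slc2a1, up by 3.37 (SE 0.15), and the type I interferon list all 24, with a median of 2.78 (adjusted p = 4.22e-28), such as Oas3, up by 4.16 (SE 0.24). Both held, at adjusted p = 0.000374 and 0.0361 with an estimated correlation. All 15 immediate early genes rose, with a median of 2.77 (adjusted p = 8.91e-13, and adjusted p = 0.0747 with an estimated correlation). In the cholesterol synthesis list 12 of 15 rose, with a median of 1.39 (adjusted p = 1.27e-05, and adjusted p = 0.331 with an estimated correlation). Markers of other cells moved along. The macrophage markers had 9 of 10 higher, with a median of 4.28 (adjusted p = 3.22e-06, and adjusted p = 0.331 with an estimated correlation), and all 10 B cell markers were lower, with a median of -7.13 (adjusted p = 2.32e-13, and adjusted p = 0.0613 with an estimated correlation). Adjusted over the list alone, these counts were the same. The count of 6583 was 4375 without the 2 splenic libraries of conflicting age labels, which leaves 1 splenic library at 3 months.

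**Figure D5:**
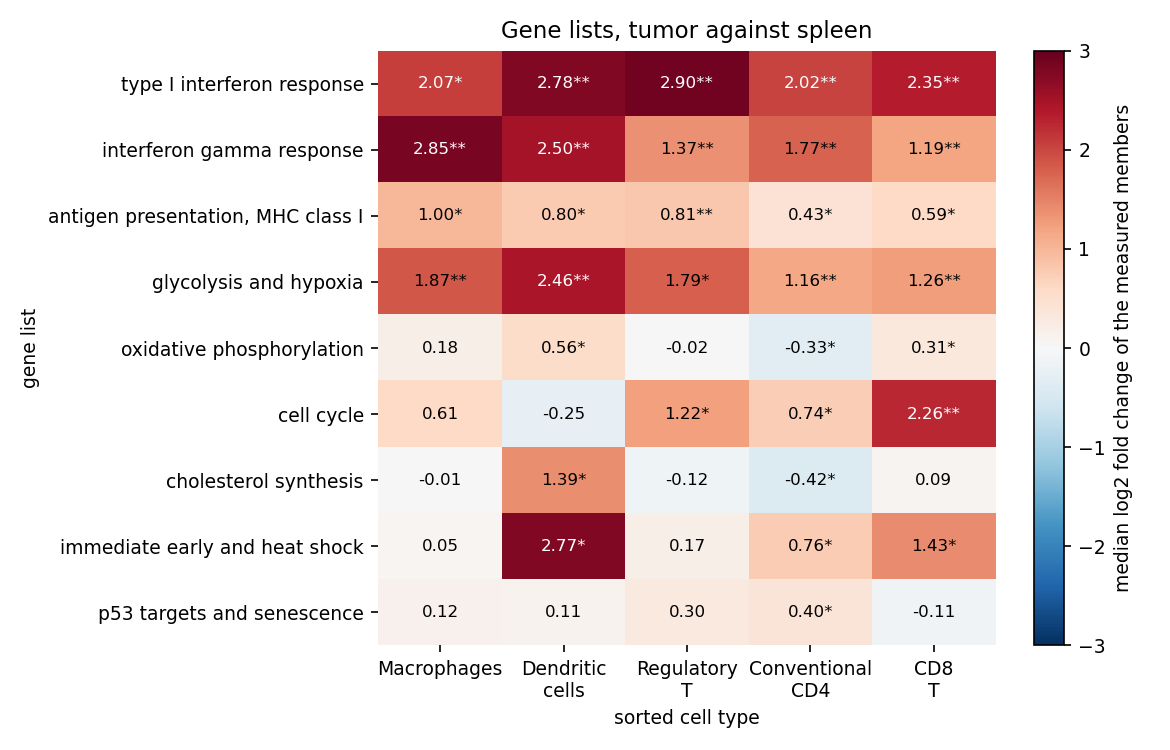
Median log2 fold change, tumor over spleen, of 9 gene lists (vertical axis) in the 5 sorted cell types (horizontal axis), as color and number, with 1 star for a camera adjusted p under 0.05 and 2 stars where it also held with an estimated correlation. The type I interferon list has medians from 2.02 to 2.90 and the glycolysis list from 1.16 to 2.46, and the cell cycle list has 2 stars in CD8 T cells only, at 2.26.

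In spleen dendritic cells, 56 genes rose and 19 fell of 12650 tested between 12 and 3 months (n = 3 libraries each, 1 male in each group). The interferon-induced GTPase gene Gbp7 rose from 41.4 ± 6.28 to 97.3 ± 18.5 CPM (SD), by 1.25 (SE 0.20), and Fcrl5, a receptor gene of B cells, rose from 13.4 ± 10.5 to 83.9 ± 7.63 CPM. The monocyte genes Ly6c2 and Ccr2 fell, Ly6c2 from 208 ± 22.4 to 102 ± 35.5 CPM, by 1.03 (SE 0.18), and Ccr2 by 0.87 (SE 0.18), while Serpinb10 fell from 54.3 ± 29.6 to 12.1 ± 2.26 CPM. B cell markers stood beside these genes, with 0 of 10 past the threshold, 7 higher over the list alone and a median of 1.81 (adjusted p = 6.54e-14, and adjusted p = 0.408 with an estimated correlation). Plasma cell markers summed to 6413 to 8353 CPM in single libraries at 12 months and 1765 to 5412 CPM at 3 months, with 0 of 7 past the threshold, 2 higher over the list alone and a median of 1.48 (adjusted p = 0.00198, and adjusted p = 0.408 with an estimated correlation). In the monocyte list 2 of 9 fell by both counts, with a median of -0.37 (adjusted p = 0.000846, and adjusted p = 0.408 with an estimated correlation). The count of 75 was 14, 0 and 8 without replicates 3, 4 and 1 at 12 months, and 444 and 7 without replicates 4 and 1 at 3 months. Each of the 5 named genes lost its call without any one of replicates 1, 3 and 4 at 12 months or replicate 1 at 3 months, and Ccr2 also without replicate 3 at 3 months. The count was 0 with all 4 groups in one fit, 303 with DESeq2 and 425 without a low-count filter. It was 0 with the age tags in place of the titles and 342 without the 2 libraries of conflicting labels, and both of these fits leave 1 library, a male, at 3 months that is assumed to vary like the 12-month group. It was 11 with the B cell marker level as a covariate.

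In tumor dendritic cells 0 of 12090 genes passed between the ages with edgeR (n = 3 libraries at 12 months and 4 at 3 months), 158 had an unadjusted p under 0.05, and DESeq2 called 2 and edgeR without a low-count filter 4. Il1b stood at 3270 ± 742 CPM at 12 months and 4110 ± 1280 CPM at 3 months, a log2 fold change of -0.39 (SE 0.26), and Cd14 had -0.39 (SE 0.28). The inflammatory myeloid list had a median of -0.33 (adjusted p = 0.000182, and adjusted p = 0.527 with an estimated correlation). For the interaction 0 of 13981 genes passed with edgeR, 778 had an unadjusted p under 0.05, and DESeq2 called 3 and edgeR without a low-count filter 50, while B cell markers had a median of -1.69 (adjusted p = 0.000942, and adjusted p = 0.52 with an estimated correlation). Without replicate 2 of both ages, the libraries rich in macrophage transcripts, 3 genes passed in tumor and 4 in the interaction. The interaction count was 1 without tumor replicate 2 at 12 months and 2 without spleen replicate 4 at 3 months.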

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

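The tests of the ribosome-rich libraries on the ribosomal genes, of natural killer cells, of B cells and of wrong age labels, and the splits of the samples for the age effects, were chosen after the result was seen.

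In spleen conventional CD4 T cells, checkpoint, memory and T helper genes were higher at 12 months, and 67 ribosomal protein and 5 oxidative phosphorylation genes were lower. Regulatory T cells inside the CD25-negative gate are argued against as the main source of the 19 called members of these 3 lists. Foxp3 gained from 32.5 ± 11.8 to 71.5 ± 13.4 CPM, against 973 ± 63 CPM in spleen regulatory T cells. That gain allows an added share of 4.15%, if such cells resemble sorted regulatory T cells and libraries of both sorts are alike in make-up. This accounts for a median of 1.63% of the gain of the 19, and of 2.65% with the most extreme single libraries. Il2rb had the highest value, at 45.2%, or 73.7% with single libraries. The higher genes of the activated Treg list were not part of this test, so that such cells stay open for them. The 2 ribosome-rich libraries at 3 months are argued against as the whole source of the higher genes, whose median went from 2.04 (SD 1.03) to 1.84 (SD 1.88) without them, with 11 of 19 still called. For the 72 lower genes they remain a candidate explanation that this test cannot decide. The median of these genes went from -1.29 (SD 0.26) to -0.18 (SD 0.11) against the third library alone. The 2 libraries were picked by their ribosomal share, and 67 of the 72 are ribosomal protein genes, so that a smaller change was fixed in advance. Other genes with transcripts under 1000 bases, 876 in all, had a median of -0.62 (SD 0.81) against 0.04 in 10417 longer ones. Ribosomal pseudogenes and oxidative phosphorylation genes outside the list were not removed from these other genes. Their median therefore cannot tell a gain of short transcripts in those libraries from the ribosomal change itself. Only 31 of the 72 lower genes have a longest transcript under 1000 bases. Age itself stays open and untested for both parts. Only 1 of 35 splits of the samples, the real one, reached 460 genes, with 1 as the highest of the others. That is the smallest share 35 splits can give. It is not adjusted for the number of comparisons and takes the libraries as independent.

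Cytotoxic and memory genes were higher at 12 months in spleen CD8 T cells. Natural killer cells in the sort are argued against, since Tyrobp and Fcer1g, abundant in those cells, gained 8.78 CPM together, 6.06% of the gain of 145 CPM in Klrk1, and 18.8 CPM with the most extreme single libraries. Ncr1 had no count at either age, and Klrb1c, which T cells can also express, stood at 17.1 ± 4.05 against 5.37 ± 2.11 CPM. Of 35 splits, 1, the real one, reached 119 genes and the highest other gave 1, again the smallest share these splits can give, with the same limits. A larger share of memory cells among the sorted CD8 T cells and a change within cells both stay open, as does age itself, untested.

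In spleen dendritic cells 56 genes were higher at 12 months, and B cell markers stood beside them, with 0 of 10 past the threshold and 7 higher over the list alone (adjusted p = 6.54e-14, and adjusted p = 0.408 with an estimated correlation). B cells in the sort remain a candidate explanation, since all 10 B cell markers had a positive fold change with a median of 1.81 (SD 0.38) and the median of the 56 higher genes went from 1.46 (median SE 0.24) to 0.86 (median SE 0.44) with the marker level as a covariate, which decides neither way. Wrong age labels cannot be told apart from it, as 0 genes were called with the 2 libraries placed at 12 months and 342 without them, and both fits leave 1 library, a male, at 3 months that is assumed to vary like the 12-month group. The 10 splits of the 6 samples are too few for a share under 0.05, with 75 genes for the real one, the 1 split that reached it, and 11 for the highest other. Age itself stays open and untested.

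For the other comparisons the splits read as follows. For tumor against spleen 1 of 40 splits, the real one, reached the count in each type. The highest others were 0 in macrophages, dendritic cells and regulatory T cells, 11 in CD8 T cells and 309 in conventional CD4 T cells. Real counts were 6654, 6583, 7138, 5594 and 3990. Splits that mix tumor and spleen libraries in a group raise its spread, so that the low counts of the others say little about chance. For the interaction in conventional CD4 T cells 1 of 40 splits, the real one, reached the count of 98, with 1 as the highest other. That is the smallest share 40 splits can give. Chance cannot be excluded for the interaction in CD8 T cells, where 3 of 40 splits gave at least 19 genes and the highest other gave 36. The splits with 36 and 27 genes each moved 12 of the 16 libraries, so that most ages were swapped in at least 1 tissue. Such splits keep much of an age contrast, which limits what this share says about chance. Nor can chance be excluded for age in spleen regulatory T cells, where 2 of 35 splits gave at least 6 genes. There the highest other, numbers 1 and 3 against 2 and 4 of both ages, gave 41. With the replicate number as a block that comparison gave 12 genes. Where the real count is 0 the splits decide nothing about chance, since all of them reach it. This covers the 35 splits each for age in tumor macrophages, spleen macrophages, tumor dendritic cells, tumor regulatory T cells and tumor CD8 T cells, with highest others of 115, 8, 691, 121 and 1, and the 40 each for the interaction in macrophages, dendritic cells and regulatory T cells, with 1, 18 and 7. The splits with 115, 691, 121 and 41 genes may reflect a structure of the samples other than age, which was not tested. That of 691 parts the tumor dendritic cell libraries numbered 3 or 4 from those numbered 1 or 2. The split with 121 parts numbers 1 and 2 from 3 and 4 of both ages in tumor regulatory T cells, where the replicate block gave 3 genes.

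Single libraries lay far from the other 3 of their group in 14 of 147 group and measure pairs tested. Marker sums were tested only where the highest library of the group reached 100 CPM. A single high library could thus bring its own pair into the test, so that the 14 cannot be set against a rate expected by chance. In tumor dendritic cells at 3 months, replicate 2 had 21130 CPM of macrophage markers (others 7004 to 9316) and 123 CPM of platelet markers (10.5 to 23.2). Replicate 3 of that group had 522 CPM of erythroid markers (0.252 to 0.658). In spleen macrophages at 12 months, mitochondrial genes took 1.38% of counts in replicate 4 (0.817% to 0.901%) and macrophage markers summed to 17890 CPM in replicate 3 (23250 to 23950). In tumor macrophages at 12 months, ribosomal protein genes took 1.22% in replicate 3 (0.919% to 0.958%) and fibroblast markers summed to 909.6 CPM in replicate 4 (28.1 to 46.0). Spleen macrophages at 3 months had 215 CPM of erythroid markers in replicate 3 (5.25 to 12.2). Tumor macrophages at 3 months had 103 CPM of T cell markers in replicate 1 (4.02 to 16.5) and 203 CPM of epithelial markers in replicate 4 (21.3 to 49.9). Mitochondrial genes took 10.9% in replicate 4 of tumor conventional CD4 T cells at 12 months (6.04% to 6.71%) and 2.01% in replicate 2 of spleen regulatory T cells at 3 months (1.80% to 1.83%). Erythroid markers summed to 170.5 CPM in replicate 3 of spleen CD8 T cells at 3 months (2.02 to 4.16), and NK cell markers to 304 CPM in replicate 3 of tumor CD8 T cells at 3 months (127 to 141).

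The age effect differed between tumor and spleen for 98 genes in conventional CD4 T cells. Among them, interaction log2 fold changes were -3.66 for Bhlhe40, -5.17 for Itgb8, -3.79 for Cd83, -2.66 for Irf8, -1.93 for Gbp3, -2.17 for Rrm2, -3.13 for Pmaip1 and -3.47 for Rgs16. They were -1.79 for Pdcd1, -2.78 for Tigit, -2.54 for Ctla4, -3.19 for Itgae, -2.42 for Ccr8, -1.95 for Prdm1, -2.28 for Ikzf2 and -1.51 for Tnfrsf4. Maf had -2.63, Il2rb -1.32 and Tbc1d4 -1.58, while mt-Nd2, a gene of the mitochondrial genome, and Lars2, a nuclear gene of a mitochondrial tRNA synthetase, had 1.41 and 1.79. Of these, Gbp3, Ikzf2 and Maf lost their call without tumor replicate 1 at 3 months, which like the loss of replicate 3 leaves 1 library in that group, and Prdm1, Ctla4, Tnfrsf4, Il2rb and mt-Nd2 without that library or spleen replicate 1 at 3 months. Tnfrsf4, Il2rb and mt-Nd2 also lost it without tumor replicate 3 at 3 months, Ctla4 and Il2rb without spleen replicate 1 at 12 months, Il2rb without spleen replicate 4 at 12 months, and mt-Nd2 without spleen replicate 3 at 12 months or spleen replicate 4 at 3 months. Lars2 lost it without any one library except spleen replicate 2 and tumor replicates 3 and 4 at 12 months and spleen replicate 3 at 3 months, Rrm2 without any one except spleen replicates 2 and 3 and tumor replicate 4 at 12 months and spleen replicate 3 at 3 months, and Tbc1d4 without any one except spleen replicate 1 and tumor replicate 2 at 12 months and spleen replicate 3 at 3 months. By list, the median interaction was -1.26 for checkpoint, -1.14 for tissue residence, -1.20 for activated Treg and -1.02 for memory genes. If all Foxp3 of this sort came from regulatory T cells, their share, as a ratio of Foxp3 levels, went from 25.2% at 3 months to 12.9% at 12 months in tumor. In spleen it went from 3.01% to 7.36%. Whether such cells account for part of the interaction was not tested.

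In CD8 T cells the interaction passed the threshold for 19 genes, a count for which chance cannot be excluded, with 3 of 40 splits at 19 or more. Interaction log2 fold changes were -2.33 for Klrk1, -2.97 for Klrc2, -2.08 for Fasl, -2.67 for Klrc1, -2.30 for Bhlhe40 and -0.99 for Cd44. Ccl5 had -1.72 and lost its call when any one of 10 single libraries was left out, spleen replicates 1 and 3 and tumor replicates 1 and 4 at 12 months, and spleen replicates 2, 3 and 4 and tumor replicates 1, 2 and 3 at 3 months. By list, the median interaction was -1.72 for cytotoxic, -1.15 for tissue residence and -0.76 for memory genes and -1.73 for NK cell markers.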

How the results depend on the processing

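The fits with a ribosomal or B cell covariate, without ribosomal protein genes, without the ribosome-rich libraries and without replicates 2 or 4 were chosen after the result was seen. Of 583 gene list tests 202 were past the threshold with the preset correlation and 62 with an estimated one. DESeq2 size factors kept 580 of 583 lists, and the replicate block 537 of 582, with 31 newly past the threshold. Lists and genes past the threshold in neither fit count as kept here and below, whatever their sign. Among the 1087 named gene values, size factors kept 1079, no filter 1055, the Wald test 1060 of 1080 and the replicate block 1037. None of the values past the threshold in either of the fits compared was reversed. The ribosomal covariate kept 159 of 222, with 52 no longer past the threshold and 8 reversed, and leaving out the ribosome-rich libraries 172 of 222, with 45 and 1. The B cell covariate and the age tags kept 35 of 48 each, all 4 groups in one fit 382 of 415, and leaving out 1 library 12485 of 12932 values, with 355 no longer past the threshold. Simulated recovery of a log2 fold change of 1 was 2.1% and 3.2% for the interaction in conventional CD4 T cells and dendritic cells, so small changes there mostly go undetected, and the parts of depth and sample number in this were not tested. Values below are numbers of genes called, and the cause was not tested unless stated.

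Without a low-count filter, counts for age in tumor, age in spleen and the interaction were 43, 53 and 5 in macrophages, 4, 425 and 50 in dendritic cells, 41, 56 and 13 in regulatory T cells, 51, 839 and 261 in conventional CD4 T cells and 39, 192 and 81 in CD8 T cells. With the DESeq2 Wald test they were 3, 12 and 1 in macrophages, 2, 303 and 3 in dendritic cells, 7, 26 and 5 in regulatory T cells, 40, 881 and 200 in conventional CD4 T cells and 12, 192 and 48 in CD8 T cells. The replicate block gave 6 for age in spleen macrophages, 153 for age in spleen and 3 for the interaction in dendritic cells, and 3 and 12 for age in tumor and spleen in regulatory T cells. Each of the 4 libraries correlated best with its own number across the ages in spleen regulatory T cells and tumor CD8 T cells, and 3 of 4 did in tumor regulatory T cells, a hint from the data. It gave 114 for age in tumor conventional CD4 T cells, and 9 for age in tumor and 33 for the interaction in CD8 T cells. With all 4 groups in one fit, age gave 0 in spleen dendritic cells, 3 in tumor and 3 in spleen regulatory T cells, 8 in tumor conventional CD4 T cells, and 3 in tumor and 75 in spleen CD8 T cells.

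Age in spleen dendritic cells gave 47 without the sex covariate, 342 without the libraries of conflicting labels, 0 with their age tags and 11 with the B cell covariate, and tumor against spleen gave 4375 without those libraries. Leaving out number 2 gave 3 in tumor dendritic cells and 4 in the interaction, and leaving out number 4 gave 1 in tumor regulatory T cells and 4 in tumor CD8 T cells. With the ribosomal covariate conventional CD4 T cells gave 47 for age in spleen, 1619 for tumor against spleen and 55 for the interaction, and 79, 2465 and 43 without the ribosome-rich libraries, where fewer samples were fitted.

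Leaving out each library in turn gave, for age in tumor, age in spleen, tumor against spleen and the interaction, 0 to 2, 0 to 0, 6390 to 6869 and 0 to 1 in macrophages, 0 to 0, 0 to 444, 5797 to 6560 and 0 to 2 in dendritic cells, and 0 to 0, 2 to 8, 6838 to 7332 and 0 to 2 in regulatory T cells. It gave 0 to 11, 88 to 2400, 2820 to 4517 and 24 to 640 in conventional CD4 T cells and 0 to 2, 72 to 138, 5233 to 5733 and 12 to 29 in CD8 T cells.

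Some values reversed. The type I interferon list for age in tumor conventional CD4 T cells had a median of -0.188 with the replicate block. With the ribosomal covariate in conventional CD4 T cells, which removes part of the ribosome-rich difference by construction, log2 fold changes for age in spleen were 0.08 for Cox4i1, 0.15 for Cox6c, 0 for Mif and 0.11 for Ndufa4, and for tumor against spleen 0.51 for Atp5o, 0.91 for Cox4i1, 1.05 for Mif and 0.66 for Psme1. Without the ribosome-rich libraries Cox6c had 0.04 for age in spleen.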

Other observations

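The tests of regulatory T cells inside the tumor conventional CD4 sort were chosen after the result was seen.

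In T cells of all 3 sorted types, Cxcr6, Cd274 and Tap1 were higher in tumor than in spleen. The chemokine receptor gene Cxcr6 rose from 220 ± 35 to 1520 ± 539 CPM (SD) in CD8 T cells (n = 8 libraries each), from 120 ± 25.7 to 1270 ± 477 CPM in conventional CD4 T cells (n = 7 and 6) and from 11.8 ± 7.63 to 653 ± 214 CPM in regulatory T cells (n = 8 each). Cd274, which encodes the checkpoint ligand PD-L1, rose by 1.67 (SE 0.12), 2.00 (SE 0.17) and 1.77 (SE 0.10), and the peptide transporter gene Tap1 by 1.11 (SE 0.08), 1.10 (SE 0.14) and 1.35 (SE 0.07). In the tissue residence list of CD8 T cells 10 of 12 members rose and 1 fell, 11 and 1 over the list alone, with a median of 2.90 (camera adjusted p = 1.42e-21, and adjusted p = 0.000156 with an estimated correlation). In regulatory T cells Bcl6 and Cxcr5, genes of follicular helper cells, fell by 2.91 (SE 0.37) and 2.46 (SE 0.30), and Tbc1d4 fell from 329 ± 70.9 to 4.11 ± 2.79 CPM. Conventional CD4 T cells of the tumor also carried cytotoxic genes, with 18 of 21 higher, 19 higher and 1 lower over the list alone, and a median of 3.48 (adjusted p = 2.47e-16, and adjusted p = 0.0241 with an estimated correlation). Regulatory T cells in this sort, at the share given by Foxp3 below, would account for 85.2% of the gain of Gzmb and 0.296% of that of Ifng. That share exceeds the gain of some other genes, so that these values may be too high.

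Among genes of antigen presentation, tumor macrophages (n = 8 libraries each) had 13 of 14 class I genes higher, with a median of 1.00 (adjusted p = 1.77e-07, and adjusted p = 0.128 with an estimated correlation), and H2-D1, the other one, had a log2 fold change of 0.01 (SE 0.09). Of 12 class II genes 9 rose and 3 fell (adjusted p = 0.00657, and adjusted p = 0.534 with an estimated correlation), the protease gene Ctss rising by 2.22 (SE 0.10) and H2-Oa and H2-Ob, which encode an inhibitor of peptide loading that B cells express, falling by 3.62 (SE 0.30) and 3.67 (SE 0.29) beside all 10 B cell markers, whose median was -8.32. Tumor dendritic cells (n = 7 and 6) had higher Cd86, up by 1.68 (SE 0.14), and higher Fcgr1, from 1.89 ± 0.991 to 428 ± 145 CPM. Fcgr1 is one of the macrophage markers, which summed to 4011 to 23770 CPM in single tumor libraries of this sort and 1118 to 1910 CPM in splenic ones. In the mature dendritic cell list 11 of 15 rose and 1 fell (median 0.73, adjusted p = 0.00141, and adjusted p = 0.487 with an estimated correlation), and all 6 plasmacytoid markers were lower (median -3.54, adjusted p = 0.00497, and adjusted p = 0.331 with an estimated correlation). Counts of these lists adjusted over the list alone were the same.

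Regulatory T cells inside the CD25-negative gate may account for part of the regulatory genes of tumor conventional CD4 T cells. The estimate assumes that all Foxp3 came from such cells, at the level of sorted regulatory T cells of the same tissue and age. The ratio of Foxp3 levels then gives a share of 25.2% in the tumor sort at 3 months and 12.9% at 12 months. In the spleen sort it gives 3.01% and 7.36%. This ratio of transcripts equals a share of cells only if RNA per cell and library make-up are alike. Library make-up differed, as mitochondrial genes took 0.865% to 2.01% of counts in regulatory T cells and 5.06% to 10.9% in conventional CD4 T cells. For tumor over spleen, the share accounts for a median of 38.4% of the gain of the 17 called activated Treg members other than Foxp3. Of these, 3 members were at 80% or more and 11 under 50%. With the most extreme single libraries the median is 63.5%, with 6 members at 80% or more and 3 under 50%. For 12 against 3 months in tumor, it accounts for a median of 44.8% of the loss of the 7 members other than Foxp3 that were lower over the list alone, and of 99.1% with the most extreme single libraries. Neither value decides, so that a share of regulatory T cells stays open for both, next to a change within conventional cells, tissue and age, which were not tested. By gene, the same share would account for 85.2% of the gain of Gzmb in tumor, 86.2% of that of Havcr2 and 37.2% of that of Il10. For the gains of Ifng and Csf2 it would be 0.296% and 0.117%, and for Tnfrsf9 74.3%. The share exceeds the observed change of Itgae, at 162% of the gain in tumor and 138% of the loss with age. It also exceeds the gain of Lrrc32, at 137%, and the losses of Il2ra and Izumo1r, at 129% and 105%. At 3 months tumor regulatory T cells held Itgae at 1358 CPM (TMM-scaled). A share of 25.2% would exceed the 270.4 and 186.9 CPM of the conventional CD4 libraries. The assumption thus fails for Itgae, and the percentages of other genes may be too high.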
